A study of Homo sapiens with 6 samples.

How the data were processed

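Poly(A) RNA of C918 cells was extracted with QIAzol and made into libraries with a stranded Illumina mRNA kit, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, RSEM and DESeq2 and the build GRCh38.p13, with no versions. Their roles, the aligner settings, the annotation release and the strand setting are not given in the sources used here. The authors deposited 1 table of the whole series, named for raw counts, whose values are TPM, as each column sums to 1000000 within 1, with 2 decimals. TPM keeps no depth, so the depth per library and the counting precision are unknown, and tools that need counts were not used. The test planned before the values were seen assumed counts, and limma on log2 values replaced it.

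The table held 62703 genes in 6 libraries, 3 controls (phosphate-buffered saline) and 3 with 400 µM tetracaine, all for 24 h, grouped by the titles in the labels. No pair of libraries held identical columns. Gene symbols came from the deposited table, and coordinates, biotypes, GC content and transcript length from GENCODE v29 on GRCh38, which held 58279 of the gene identifiers and 15465 of the 16119 tested. Genes with 0.5 TPM or more in at least 3 libraries were tested. Libraries were scaled by unweighted trimmed means of log ratios (30% of log ratios and 5% of abundances trimmed from each end), and values so divided are called scaled TPM. log2(scaled TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options, two-sided), group being the only term, and Benjamini-Hochberg adjusted p under 0.05 was called. Exact permutation of 3 against 3 libraries cannot give a p below 0.1, so no permutation test per gene was run. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

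The 30 gene lists (620 symbols, all matched) were fixed before the data were examined: cholesterol, fatty acid, ATF4, endoplasmic reticulum, lysosome, autophagy, mitosis, DNA replication, p53, apoptosis, nuclear and mitochondrial respiratory chain, glycolysis, hypoxia, NF-kB, interferon, NRF2, heat shock, matrix, MAP kinase, YAP, ribosome biogenesis, calcium, histone, sodium channel and cell type marker lists. Lists with at least 5 tested members entered limma's camera with a preset correlation of 0.01, adjusted over 24 lists. The rule for named genes, fixed at the same time, took first the 10 called protein-coding genes with the largest change in each direction, with a mean of 5 TPM or more and no overlap between groups. It then took per list up to 3 called members with the smallest p and 1 called against the majority, or the most abundant member where none was called, and a fixed set of genes whatever their values (HMGCS1, DDIT3, ATF3, CDKN1A, MKI67, MITF, SQSTM1, HMOX1 and CCND1). Some genes that the rule names are not reported here. Other genes the text names were chosen after their values were seen.

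The steps were tested on simulated data for this comparison, with 16119 genes of which 200 were changed, in 5 runs. The test recovered 0% of genes changed by 0.5 log2, 29.9% at 1 and 69.1% at 2, and 3.81% of calls were false. In these runs 0 of 200 unchanged lists were called. The errors were drawn independently for each gene and no library was made to stand apart. The runs therefore cannot show how the list test behaves where genes of a list vary together.

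Alternatives covered other scaling factors, filters on low values, pseudocounts of 0.1 and 5 TPM, each library left out, the replicate number as a block, smooth correction for GC content and length (splines with 5 degrees of freedom), protein-coding genes only, stricter thresholds, library weights and other list tests. KEGG terms of the deposited annotation with at least 10 tested members were tested with camera after the data were seen. Random lists for comparison were 10000 per list, matched on mean expression, GC content and transcript length. Reference sequence for promoter searches was not used here.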

Results

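Messenger RNA was sequenced from C918 cells, a human uveal melanoma line, after 24 h with tetracaine hydrochloride at 400 µM or with an equal volume of phosphate-buffered saline. Tetracaine is a local anaesthetic that blocks voltage-gated sodium channels. Each group held 3 libraries, which the series text calls biological replicates. The titles of the samples read C918, while the cell line field of the labels reads C198. The deposited values were TPM, a length-adjusted share of all transcripts, so the sequencing depth was unknown and no counting interval could be given. Between 13024 and 14367 genes reached 1 TPM in a library.

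Control library 3 stood apart from the other libraries. Across the tested genes, which are not independent replicates, it correlated at 0.940 and 0.942 with control libraries 1 and 2 and at 0.919 to 0.928 with the tetracaine libraries. Control libraries 1 and 2 correlated at 0.989 with each other and at 0.962 to 0.963 with the tetracaine libraries, and every pair of tetracaine libraries correlated at 0.989. Mitochondrially encoded genes held 10.2%, 9.54% and 7.38% of the TPM in control libraries 1, 2 and 3 and between 7.23% and 7.97% in the tetracaine libraries. The composition factor of control library 3 was 0.719, against 1.01 to 1.14 in the other 5 libraries.

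**Figure D1:**
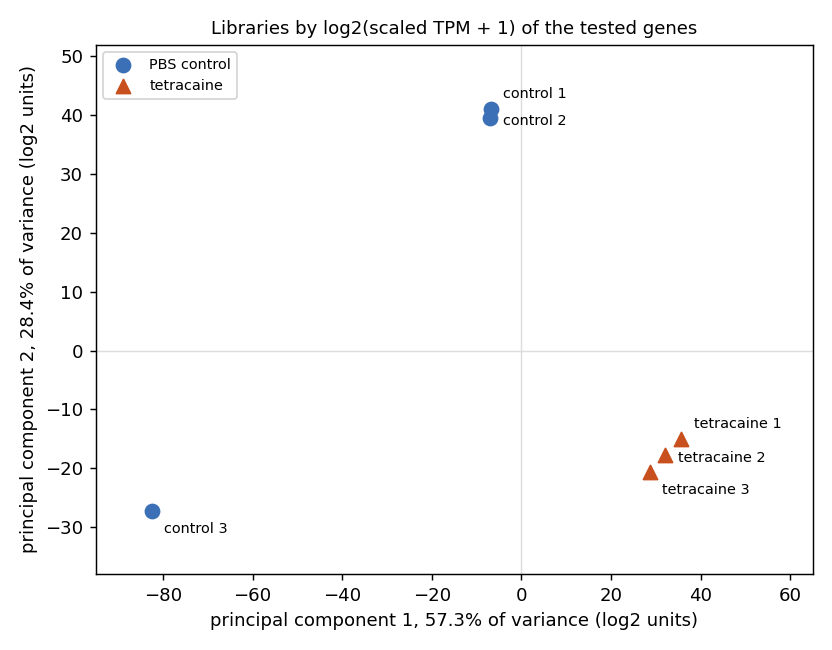
Position of the 6 libraries on principal components 1 (57.3% of the variance) and 2 (28.4%) of log2(scaled TPM + 1), in log2 units; blue circles are controls and orange triangles tetracaine. Controls 1 and 2 lie together, the 3 tetracaine libraries lie together, and control 3 lies away from both.

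The comparison asked which transcripts differ between tetracaine-treated and control C918 cells. MMP1, an interstitial collagenase, rose from 0.992 ± 0.245 to 270.1 ± 7.50 scaled TPM (mean ± SD, n = 3 per group). CXCL8, a neutrophil-attracting chemokine, rose from 3.67 ± 0.990 to 172 ± 8.46 scaled TPM. IGFBP3, a secreted binder of insulin-like growth factors, fell from 64.5 ± 2.36 to 4.29 ± 0.476 scaled TPM. Of 17 measured inflammatory targets of NF-kB 16 rose, of 24 genes of cholesterol synthesis and uptake 13 rose, and of 31 DNA replication genes 19 fell.

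Among 16119 genes tested with limma, 1730 had an adjusted p under 0.05, with 1034 higher and 696 lower in tetracaine. Of these, 523 rose and 284 fell by at least 2-fold on the log2(TPM + 1) scale, which understates the change of low genes. The 3 libraries of each group did not overlap for 6582 genes (40.8%), where chance gives 10%. Leaving out the composition factors shifted the median of all genes by 0.22 log2 and gave 1410 higher and 364 lower genes, so that 79.5% of calls were higher in place of 59.8%. The fit without control library 3 called 6838 genes, 3495 higher and 3343 lower, and held 1729 of the 1730 genes in the same direction. Leaving out control library 1 or 2 gave 835 or 792 calls, and leaving out tetracaine library 1, 2 or 3 gave 384, 366 or 404.

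The 10 genes with the largest rise under the naming rule were MMP1, CXCL8, HTN3, IL4I1, SCG5, TM4SF19-DYNLT2B, HTN1, MMP9, STC1 and ICAM1. The rule itself required all 3 tetracaine libraries to lie above all 3 controls. MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160, GRCh38) rose by 7.10 ± 0.14 log2 (SE, n = 3 per group; limma adjusted p = 2.04e-05). CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) rose by 5.23 ± 0.18 (limma adjusted p = 0.000242). HTN3 and HTN1, neighbouring genes for salivary histatins, rose by 4.43 and 3.79 to 26.0 ± 5.15 and 13.8 ± 2.10 scaled TPM (limma adjusted p = 0.000640 and 0.000370). These paralogs resemble each other closely, so the split of reads between them is uncertain. IL4I1, a secreted amino acid oxidase, rose by 4.24 ± 0.15 and the secretory granule chaperone SCG5 by 3.93 ± 0.32. MMP9, a gelatinase, rose by 3.74 ± 0.16, and STC1, a secreted glycoprotein hormone, by 3.41 ± 0.18. ICAM1, an adhesion receptor for leukocytes, rose by 3.41 ± 0.20 from 2.48 ± 0.731 to 35.5 ± 4.01 scaled TPM. TM4SF19-DYNLT2B, a readthrough transcript that overlaps both of its parent genes and whose value is therefore uncertain, rose by 3.84 ± 0.26. The limma adjusted p of IL4I1, SCG5, TM4SF19-DYNLT2B, MMP9, STC1 and ICAM1 lay between 0.000242 and 0.00183.

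The 10 protein-coding genes with the largest fall under the naming rule were IGFBP3, KRT80, KRT7, LY6K, PLAC8, KRT81, APLN, AP1M2, SPC24 and VSTM1. The rule itself required all 3 tetracaine libraries to lie below the 3 controls. IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874, GRCh38) fell by 3.63 ± 0.13 log2 (SE, n = 3 per group; limma adjusted p = 0.000242). KRT7 (ENSG00000135480, chromosome 12, 52232520 to 52252186), an intermediate filament keratin of simple epithelia, changed by -3.00 ± 0.40 (limma adjusted p = 0.00824). Control library 3 held 1185 scaled TPM of KRT7, against 438 and 434 in control libraries 1 and 2, and without it the change was -2.51 (limma adjusted p = 3.95e-07). The keratins KRT80 and KRT81 fell by 3.02 ± 0.26 and 2.41 ± 0.41, where KRT81 shares sequence with other hair keratins and is uncertain. LY6K, a membrane-anchored antigen, fell by 2.79 ± 0.23, and APLN, the ligand of the apelin receptor, by 2.32 ± 0.15. SPC24, part of the NDC80 kinetochore complex, fell by 2.29 ± 0.28. PLAC8, AP1M2 (an epithelial clathrin adaptor subunit) and VSTM1 changed by -2.47, -2.32 and -2.28, and by -2.09, -1.69 and -1.72 without control library 3. Their limma adjusted p were 0.0108, 0.0419 and 0.0339 with all libraries. Some of these calls were lost whichever tetracaine library was left out, while the size of the change stayed alike. Without tetracaine library 1, 2 or 3 the limma adjusted p of KRT7 was 0.0556, 0.0562 or 0.0549, at changes of -3.00, -2.98 and -3.02. That of KRT81 was 0.0902, 0.0901 or 0.0845, at changes of -2.39, -2.40 and -2.45. AP1M2 reached 0.153, 0.160 or 0.146 in the same fits and 0.0557 or 0.0687 without control library 1 or 2, and VSTM1 0.136, 0.126 or 0.135 and 0.0573 or 0.0520 (limma adjusted p). PLAC8 reached 0.0659 or 0.0658 without tetracaine library 1 or 2 (limma adjusted p).

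**Figure D2:**
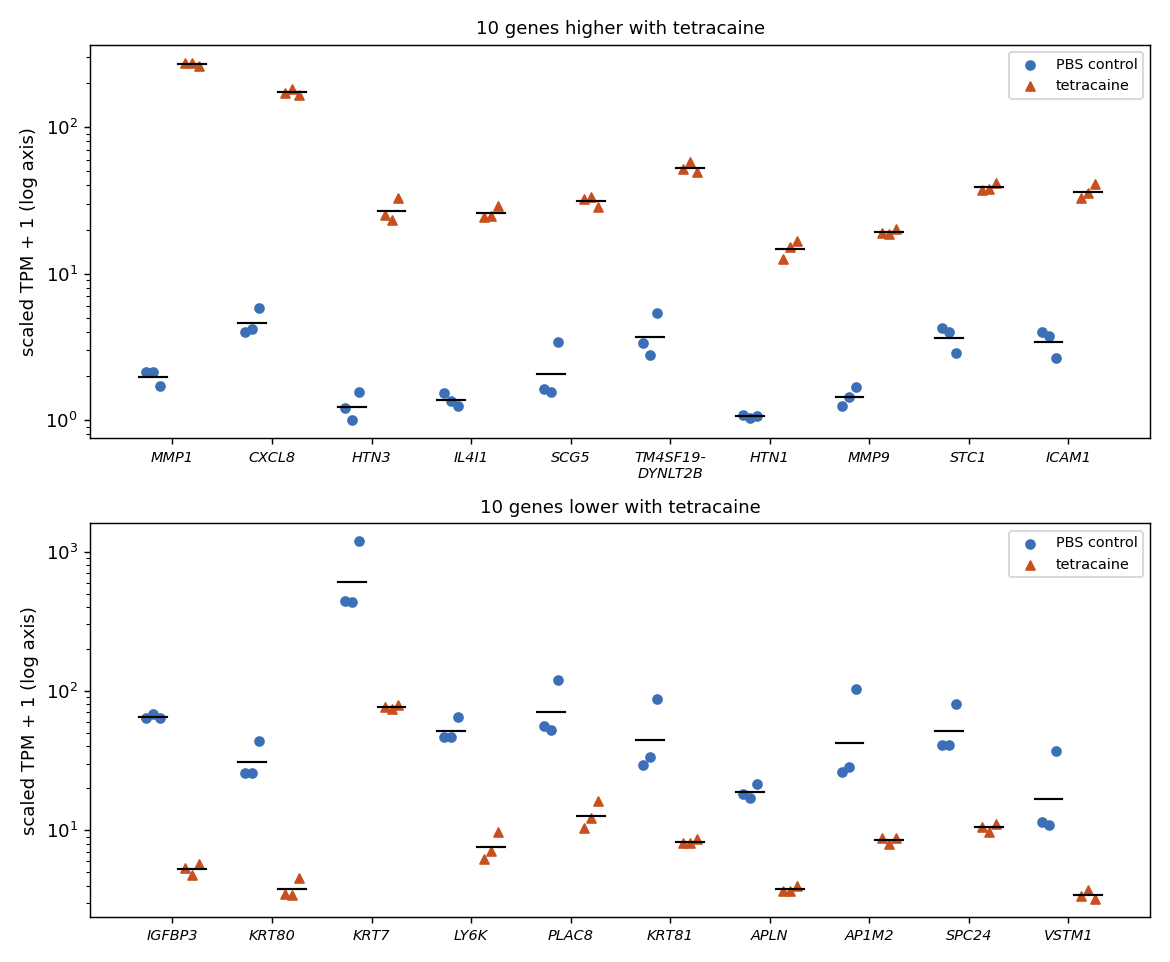
Scaled TPM + 1 on a log axis of the 10 protein-coding genes with the largest rise (upper panel) and the largest fall (lower panel) under the naming rule. Each point is 1 library (blue circles controls, orange triangles tetracaine) and black bars are geometric means of 3 libraries. The groups do not overlap for any of these genes, as the rule required. Control 3 holds the highest KRT7 value, 1185.

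Of 9 genes fixed beforehand and reported whatever their values, SQSTM1, HMOX1, DDIT3, ATF3, HMGCS1 and CDKN1A rose. SQSTM1 (ENSG00000161011, chromosome 5, 179806398 to 179838078, GRCh38), a cargo receptor of selective autophagy, rose by 2.46 ± 0.18 log2 from 416 ± 87.1 to 2259 ± 47.9 scaled TPM (n = 3 per group; limma adjusted p = 0.00121). HMOX1, the haem-degrading enzyme, rose by 3.13 ± 0.20 (limma adjusted p = 0.000871). DDIT3, the stress transcription factor CHOP, rose by 2.65 ± 0.19 (limma adjusted p = 0.00142). ATF3, a stress-induced transcription factor, rose by 2.62 ± 0.36 (limma adjusted p = 0.00906), with 0.0600, 0.0562 or 0.0576 when tetracaine library 1, 2 or 3 was left out. HMGCS1, an enzyme of the mevalonate pathway, rose by 1.84 ± 0.36 (limma adjusted p = 0.0275), with 0.0555 without control library 2 and 0.126, 0.122 or 0.108 without tetracaine library 1, 2 or 3. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.77 ± 0.12 (limma adjusted p = 0.0119), with 0.0522 or 0.0574 without control library 1 or 2 and 0.0916, 0.0902 or 0.0854 without tetracaine library 1, 2 or 3. MKI67, a marker of proliferating cells, differed by -0.99 ± 0.36 (limma adjusted p = 0.138). Its control values were 73.0, 69.0 and 28.7 scaled TPM, and without control library 3 the difference was -1.41 (limma adjusted p = 8.06e-06). CCND1, the G1 cyclin D1, differed by -0.24 ± 0.12 (limma adjusted p = 0.260), and by -0.30 without control library 3 (limma adjusted p = 0.00188). MITF, the melanocyte transcription factor, was low, at 0.678 ± 0.223 scaled TPM in controls and 1.04 ± 0.110 with tetracaine. It differed by 0.29 ± 0.15 (limma adjusted p = 0.258), on a scale that understates the change of low genes.

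Gene lists fixed before the data were examined were compared with all other tested genes by limma's camera. Of 24 lists with at least 5 tested members, 14 rose and 7 fell at an adjusted p under 0.05, and 9 and 3 of these were called with an estimated correlation. The much smaller camera adjusted p given below rest on the preset correlation of 0.01, which is an assumption. With the correlation estimated, the camera adjusted p of the lists still called lay between 0.0136 and 0.0373. The fry test, which sets each list against no change in place of the other genes, called 15 higher and 6 lower, and so gained the apoptosis list (fry adjusted p = 0.0293) and lost the nuclear respiratory chain list (fry adjusted p = 0.0604). Median, mean and camera direction had the same sign in each of the 24 lists. Log2 fold changes of members are given with their limma standard errors over 3 libraries per group.

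Inflammatory targets of NF-kB, the transcription factor of cytokine and stress signalling, rose as a list (limma camera adjusted p = 2.07e-16; adjusted p = 0.0136 with an estimated correlation). Of 17 members 16 rose, 16 also when adjusted over the list alone, and 17 rose without control library 3. IL1B, a secreted interleukin, rose by 3.13 ± 0.15, and the chemokine gene CXCL3, whose reads are uncertain because of its close paralogs, by 2.59 ± 0.13. Of 20 immediate early genes and feedback inhibitors of MAP kinase signalling 12 rose (12 adjusted over the list alone, with 1 lower), and the list rose (limma camera adjusted p = 5.35e-08). EGR1, an immediate early transcription factor, rose by 3.37 ± 0.14, the phosphatase gene DUSP5 by 1.96 ± 0.11 and PHLDA1 by 1.28 ± 0.12. Among 28 genes of the extracellular matrix and mesenchymal state 11 rose and 4 fell, with the same counts adjusted over the list alone (limma camera adjusted p = 0.00109). The stromelysin MMP3 rose by 3.32 ± 0.15 beside MMP1 and MMP9, whereas THBS1, a matrix glycoprotein, fell by 2.21 ± 0.45. With control library 3 left out, limma called 14 MAP kinase genes higher and 1 lower, and 14 matrix genes higher and 6 lower. Leaving out any other library left 9 to 12 NF-kB targets, 7 to 11 MAP kinase genes and 7 to 10 matrix genes higher and 0 lower in each list, so the calls of falling matrix genes, THBS1 included, were lost in each of these fits.

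Genes of the integrated stress response governed by ATF4, an activator of amino acid and stress genes, rose as a list (limma camera adjusted p = 5.31e-08). Of 29 members 12 rose and 1 fell, or 17 and 1 adjusted over the list alone. Beside DDIT3, the pseudokinase gene TRIB3 rose by 1.41 ± 0.12 and the mTOR inhibitor gene DDIT4 by 1.29 ± 0.12, while SLC7A5, a transporter of large neutral amino acids, fell by 0.92 ± 0.18. Of 22 chaperones and unfolded protein response genes of the endoplasmic reticulum 8 rose and 0 fell, with 8 adjusted over the list alone (limma camera adjusted p = 1.73e-05). HERPUD1, a component of endoplasmic reticulum degradation, rose by 1.94 ± 0.13, the co-chaperone gene DNAJB9 by 1.44 ± 0.21 and XBP1, a transcription factor of the unfolded protein response, by 0.86 ± 0.11. With control library 3 left out, limma called 21 higher and 2 lower in the ATF4 list and 19 higher and 1 lower in the endoplasmic reticulum list. Leaving out any other library left 5 to 8 and 2 to 5 higher, respectively, and 0 lower, so the SLC7A5 call was lost in each of these fits.

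Among 16 cytosolic heat shock genes 2 rose, HSPA1A by 0.70 ± 0.14 and HSPA1B by 0.61 ± 0.14, and 2 rose adjusted over the list alone. These encode nearly identical inducible Hsp70 proteins, so reads between them are uncertain. The heat shock list did not pass (median -0.15; limma camera adjusted p = 0.628), its median was 0.14 without composition factors, and correction for GC content and length left 0 higher and 2 lower. The fit without control library 3 called 5 higher and 8 lower, and leaving out any other library left 0.

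Lysosomal genes rose as a list (limma camera adjusted p = 7.70e-09), with 12 of 35 higher, 0 lower and 13 higher adjusted over the list alone. GPNMB, a glycoprotein of lysosomes and melanosomes, rose by 2.94 ± 0.15, the sialidase gene NEU1 by 1.99 ± 0.16 and the cholesterol-binding NPC2 by 1.42 ± 0.14. Of 26 autophagy genes 8 rose and 0 fell, 10 adjusted over the list alone (limma camera adjusted p = 7.72e-06). With SQSTM1, WIPI1, a phosphoinositide-binding autophagy protein, rose by 2.36 ± 0.14 and RRAGC, a GTPase of lysosomal nutrient sensing, by 1.68 ± 0.15. With control library 3 left out, limma called 31 higher and 2 lower among lysosomal and 20 higher and 1 lower among autophagy genes, and leaving out any other library left 6 to 10 and 5 to 8 higher.

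Genes of cholesterol synthesis and uptake rose as a list (limma camera adjusted p = 3.61e-09), with 13 of 24 higher, 0 lower and 19 higher adjusted over the list alone. INSIG1, a sterol-sensing regulator of this pathway, rose by 1.62 ± 0.15, and the enzyme genes MSMO1 and IDI1 rose by 1.38 ± 0.12 and 1.07 ± 0.13. Among 14 fatty acid synthesis genes 2 rose, FASN, the fatty acid synthase, by 0.69 ± 0.13 and LPIN1, a phosphatidate phosphatase, by 1.44 ± 0.32, and 4 rose adjusted over the list alone. The fatty acid list passed with the preset correlation (limma camera adjusted p = 0.00404), and had an adjusted p = 0.124 with an estimated correlation. The fit without control library 3 called 22 cholesterol and 7 fatty acid genes higher, and leaving out any other library left 2 to 8 and 0.

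Antioxidant genes regulated by NRF2 rose as a list (limma camera adjusted p = 7.72e-06), with 6 of 20 higher, 0 lower and 10 higher adjusted over the list alone. Beside HMOX1, the aldo-keto reductase gene AKR1C1, uncertain because of near-identical paralogs, rose by 2.46 ± 0.22, and PGD of the pentose phosphate pathway by 0.69 ± 0.12. Of 13 hypoxia response genes 5 rose, 6 adjusted over the list alone (limma camera adjusted p = 0.00211; adjusted p = 0.0893 with an estimated correlation). NDRG1, a stress-responsive gene, rose by 2.32 ± 0.23, the angiogenic growth factor VEGFA by 1.54 ± 0.21 and the mitophagy receptor BNIP3L by 0.88 ± 0.15. With control library 3 left out, limma called 13 NRF2 genes higher, and 8 hypoxia genes higher and 1 lower. Leaving out any other library left 2 NRF2 genes and 1 to 3 hypoxia genes higher.

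Cell division genes fell. Of 31 DNA replication genes 19 were lower, 0 higher and 28 lower adjusted over the list alone (limma camera adjusted p = 1.26e-16; adjusted p = 0.0136 with an estimated correlation). GINS2 and GINS1, subunits of the replicative helicase complex, fell by 1.57 ± 0.15 and 1.35 ± 0.11, and the helicase gene MCM7 by 1.23 ± 0.11. Of 28 mitosis genes 16 were lower, 0 higher and 22 lower adjusted over the list alone (limma camera adjusted p = 3.96e-15; adjusted p = 0.0253 with an estimated correlation). NDC80, a kinetochore protein, fell by 1.24 ± 0.13, and the mitotic kinase genes PLK1 and CDK1 fell by 1.19 ± 0.13 and 1.15 ± 0.12. The fit without control library 3 called 29 replication and 28 mitosis genes lower, and leaving out any other library left 6 to 17 and 6 to 12 lower.

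Among 26 ribosome biogenesis genes 7 fell and 0 rose, with 10 lower adjusted over the list alone (limma camera adjusted p = 1.05e-06). The nucleolar protein gene NCL fell by 0.73 ± 0.13, NOP16 by 0.57 ± 0.12 and DKC1, a pseudouridine synthase, by 0.55 ± 0.11. Of 10 targets of YAP, a growth-regulating coactivator, 5 fell and 0 rose, with 7 lower adjusted over the list alone (limma camera adjusted p = 5.77e-05; adjusted p = 0.111 with an estimated correlation). The matricellular genes CCN2 and CCN1 fell by 1.61 ± 0.17 and 1.55 ± 0.16, and the LIM protein gene AJUBA by 1.45 ± 0.13. With control library 3 left out, limma called 22 ribosome biogenesis and 9 YAP genes lower, and leaving out any other library left 0 and 3 to 4 lower.

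Of 52 nuclear genes of the respiratory chain 4 fell and 0 rose, with 2 lower adjusted over the list alone (limma camera adjusted p = 1.75e-08; adjusted p = 0.272 with an estimated correlation). UQCR10, ATP5MC1 and SDHD, of complexes III, V and II, fell by 0.87 ± 0.19, 0.75 ± 0.14 and 0.67 ± 0.12. Of 13 mitochondrially encoded genes 3 fell, MT-ND6 by 1.46 ± 0.21, MT-CO3 by 1.32 ± 0.24 and MT-ND5 by 1.04 ± 0.17, and 6 were lower adjusted over the list alone. Nuclear copies of mitochondrial sequence make their read assignment uncertain. The mitochondrial list had a limma camera adjusted p = 0.00100 and an adjusted p = 0.173 with an estimated correlation. Its median was -0.46, where random lists matched on expression, GC content and length, drawn after the data were seen, had a median of -0.44 (percentile 34.7). Without control library 3 these values were -0.48 and -0.19 (percentile 0.19), or -0.34 and -0.22 (percentile 10.2) when also corrected for GC content and length. For the nuclear list they were -0.55 and -0.29 with all libraries (percentile 0.01), -0.27 and -0.13 without control library 3 (percentile 0.82) and -0.30 and -0.17 when also corrected (percentile 1.28). The fit without control library 3 called 37 nuclear and 9 mitochondrial genes lower, and leaving out any other library left 0 and 0 to 3 lower.

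Among 19 glycolysis genes 2 rose and 3 fell, or 2 and 7 adjusted over the list alone (limma camera adjusted p = 0.0187 for a lower list; adjusted p = 0.0893 with an estimated correlation). The glucose transporter gene SLC2A1 fell by 1.12 ± 0.20 and the lactate dehydrogenase gene LDHA by 0.92 ± 0.16, while ENO2, an enolase, and PFKFB4, a regulator of phosphofructokinase, rose by 0.91 ± 0.11 and 1.47 ± 0.22. The glycolysis call was lost without composition factors (limma camera adjusted p = 0.0558). Its median was -0.35, where matched random lists had -0.24 (percentile 21.4), and without control library 3 these were -0.31 and -0.11 (percentile 3), or -0.34 and -0.16 (percentile 4.70) when also corrected for GC content and length. With control library 3 left out, limma called 3 higher and 12 lower, and leaving out any other library left 0 to 2 higher and 0 to 1 lower.

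Of 20 p53 target genes 2 rose, CDKN1A and BTG2, an antiproliferative gene that rose by 0.51 ± 0.12, and 4 rose and 1 fell adjusted over the list alone. The p53 list passed with the preset correlation (limma camera adjusted p = 0.0187; adjusted p = 0.0893 with an estimated correlation). Of 26 apoptosis regulators 5 rose and 1 fell, or 7 and 1 adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.0528). BIRC3, an inhibitor of apoptosis also held by the NF-kB list, rose by 3.40 ± 0.21 and PMAIP1, a pro-apoptotic BH3-only gene, by 0.65 ± 0.12, while BCL2L1, which encodes BCL-XL, fell by 0.99 ± 0.19. The fit without control library 3 called 11 higher and 2 lower in both lists and the apoptosis list passed there (limma camera adjusted p = 0.00607), as it did without tetracaine library 1 (0.0440), without composition factors (0.0304) and, among settings chosen after the data were seen, with upper-quartile factors (0.0480), a pseudocount of 5 TPM or array weights. Leaving out any other library left 0 p53 targets and 3 apoptosis regulators higher and 0 lower, so the BCL2L1 call was lost in each of these fits.

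Among 21 interferon response genes 3 rose, 8 adjusted over the list alone (limma camera adjusted p = 0.00167; adjusted p = 0.0635 with an estimated correlation). IFIT3, an interferon-induced antiviral gene, rose by 1.22 ± 0.26. The interferon median was 0.27, where matched random lists had a median of 0.05 (percentile 96.9). It stood at percentile 99.97 without control library 3 and at 99.7 when also corrected for GC content and length. Of 15 calcium channel and pump genes 4 rose, 6 adjusted over the list alone (limma camera adjusted p = 0.0141; adjusted p = 0.111 with an estimated correlation). The plasma membrane calcium pump gene ATP2B1 rose by 1.32 ± 0.26, the inositol trisphosphate receptor gene ITPR1 by 1.28 ± 0.19 and the calcium entry channel gene ORAI3 by 1.05 ± 0.17. The calcium call was lost without control library 3 (limma camera adjusted p = 0.0712), where 7 rose and 2 fell, against 12 and 1 in the interferon list. The calcium median, 0.16, stood at percentile 70.9 of matched random lists (their median was 0.08), at percentile 89.7 without control library 3 and at percentile 85.1 when also corrected for GC content and length, so the list did not stand out from matched genes. Leaving out any other library left 1 to 2 interferon and 1 to 3 calcium genes higher. Among 11 replication-dependent histone genes, most of which lack a poly(A) tail and share sequence with paralogs, 3 rose and 2 fell, also adjusted over the list alone (limma camera adjusted p = 0.687). H2AC6 and H2BC5 rose by 1.29 ± 0.29 and 1.19 ± 0.28, and H4C8 fell by 1.33 ± 0.18. Leaving out control library 3 gave 4 and 2 histone calls, and leaving out any other library 0 to 2 in each direction.

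Cell identity markers and sodium channels had fewer than 5 tested members per list and no list test. Of 18 melanocyte lineage genes only 4 were expressed enough to be tested, and 2 had a mean of 1 deposited TPM or more. Among the 4 tested, TYRP1, a melanosomal enzyme, rose by 0.84 to at most 1.96 deposited TPM, also adjusted over the list alone. No library exceeded 0.73 TPM of MLANA or 0.21 TPM of SOX10. The TYRP1 call was lost when any library other than control library 3 was left out, and 2 lineage genes rose without that control. Of 4 tested sodium channel genes 0 passed, and without control library 3, 1 of the 4 was higher and 1 lower. Among 4 tested epithelial markers KRT7, KRT8 and KRT18 fell and CLDN4, a tight junction claudin, rose by 1.28 ± 0.20, with the same counts adjusted over the list alone. KRT18 fell by 1.38 ± 0.12, whereas EPCAM and CDH1 stayed at or below 0.31 and 0.14 TPM in every library. All 4 epithelial calls held without control library 3, and leaving out any other library left 0 higher and 1 to 3 lower. Neither of 2 fibroblast nor of 2 endothelial markers passed, with FAP at 0.13 ± 0.13 and CDH5 at -0.87 ± 0.30 (limma adjusted p = 0.563 and 0.129), and CDH5 at -1.22 without control library 3 (limma adjusted p = 5.83e-05). Of 2 tested immune markers the lysosomal glycoprotein gene CD68 rose by 1.33 ± 0.15, also adjusted over the list alone, and no library exceeded 0.05 TPM of PTPRC, the pan-leukocyte marker CD45.

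**Figure D3:**
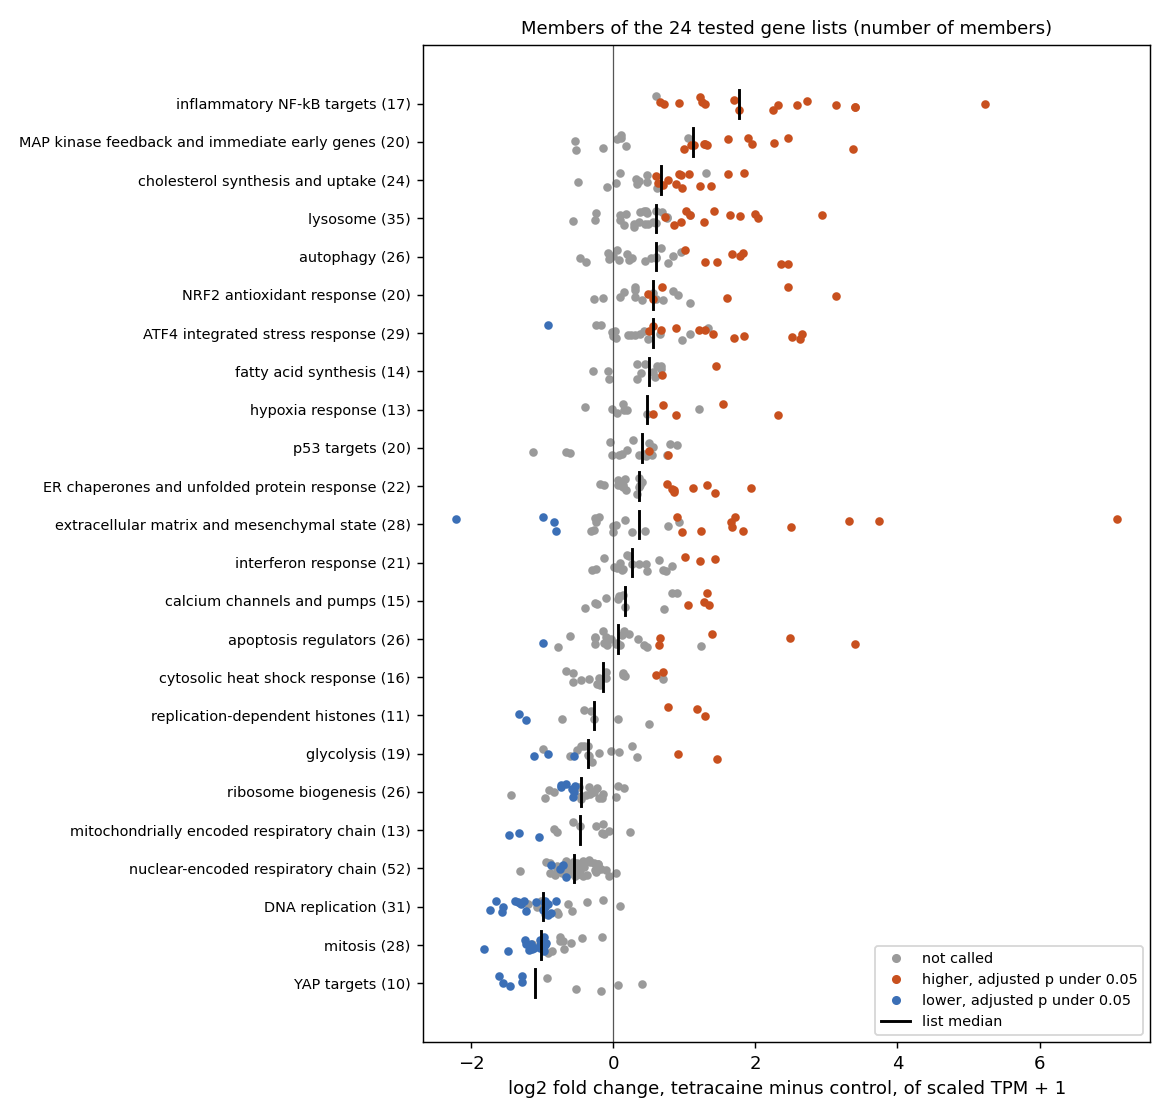
Log2 fold change (tetracaine minus control, of scaled TPM + 1) of each member of the 24 tested lists, with the number of members in brackets; points are genes (orange higher, blue lower, grey not called) and black bars list medians. The medians run from -1.10 for YAP targets to 1.78 for NF-kB targets.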

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

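Settings chosen only after the data were seen were the pseudocounts of 0.1 and 5 TPM, array weights and quantile normalization, and for lists also the GC content and length corrections and the relative log expression and upper-quartile factors; the other settings were planned. The planned DESeq2 and limma-voom fits were not run, because the values are TPM. Against 1034 higher and 696 lower genes (523 and 284 at least 2-fold), no filter gave 555 and 316, no composition factors 364 lower (147 at least 2-fold), GC content and length correction 1415 lower, a test against 1.5-fold 185 and 63, an adjusted p under 0.01 358 and 175 (317 and 146 at least 2-fold), a pseudocount of 5 TPM 260 and 155 at least 2-fold, and array weights 4036 and 3945. Leaving out 1 library gave 255 to 3495 higher and 111 to 3343 lower genes, and 248 to 623 and 110 to 383 at least 2-fold; the highest values came without control library 3. Every setting kept the direction of the genes it shared with the 1730 calls, with 0 called the opposite way. The replicate number as a block gave 520 and 296 genes. Residuals of same-numbered libraries correlated across genes at 0.130, 0.0163 and 0.170, and the best partners of controls 1, 2 and 3 were numbers 1, 1 and 3. Residuals within a group depend on each other, so these values cannot tell whether same-numbered libraries belonged together. Of 580 alternative values of 29 named genes 527 kept direction and side of the threshold, 44 lost the call, 7 gained it and 2 changed sign, both of the uncalled CCND1, which stood at 0.0461 without composition factors and 0.0246 with quantile normalization. Of 456 alternative values of the 24 lists 431 kept both, 13 lost the call and 7 gained it. The uncalled histone list changed direction by camera in 5: median 0.28 with the stricter filter, -0.022 without control library 3, where the median kept its sign, 0.0508 with GC content and length correction with or without the block, and 0.0006 with array weights. Its lowest median, -0.3448 without tetracaine library 1, was not a change of direction. An estimated correlation left 9 lists higher and 3 lower, against 14 and 7. Why calls moved was not tested, except that stricter thresholds call fewer genes by construction. Depth is unknown in TPM, so it could not be weighed for genes near 0.5 TPM.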

Other observations

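In this part the tests chosen only after the results were seen were the gene families, the pathway terms, the GC content, correlation, admixture and growth tests of control library 3 both keratin tests and, for ribosomal proteins, the correction test and the matched lists without correction; the position test, the other ribosomal protein tests and the splits of the libraries were written beforehand. Tubulins, the subunits of microtubules, were lower in 5 of 11 genes with a mean of 5 TPM or more and higher in 0. TUBA1B fell by 1.43 ± 0.17 log2 (limma SE, n = 3 per group) from 2880 to 1061 scaled TPM, TUBB by 1.12 ± 0.12 and TUBB4B by 1.02 ± 0.12; leaving out control library 3 gave 7 lower and 2 higher, any other library 2 to 5 lower, and no composition factors 3 lower and 1 higher. The signal recognition particle RNAs RN7SL1, RN7SL2 and RN7SL3, which lack a poly(A) tail and have many near-identical copies, fell by 1.77 ± 0.29, 1.73 ± 0.28 and 2.47 ± 0.30, with 3 lower without control library 3, 1 to 3 without any other library and 2 with quantile normalization. At the TM4SF19 locus all 4 tested genes rose, with TM4SF19, a tetraspanin-like membrane protein, going from 84.8 to 600 scaled TPM (2.81 ± 0.13). The 4 include the readthrough TM4SF19-DYNLT2B, which overlaps both of its parent genes, so they are not separate observations. Of these, 4 rose without control library 3 and 2 to 3 without any other library.

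Of 303 KEGG pathway terms in the deposited annotation 42 rose and 25 fell by limma's camera with the preset correlation, 63 of them also without control library 3, and 0 passed with an estimated correlation (smallest adjusted p = 0.173). Spliceosome genes were lower in 11 of 125 and higher in 3 (limma camera adjusted p = 6.25e-07; adjusted p = 0.385 with an estimated correlation). Base excision repair genes were lower in 9 of 30, homologous recombination genes in 7 of 35 and mismatch repair genes in 5 of 18, with 0 higher in each (limma camera adjusted p = 3.94e-05, 0.000750 and 3.38e-05; adjusted p = 0.268, 0.173 and 0.173 with an estimated correlation). Sphingolipid metabolism genes were higher in 5 of 37 and lower in 0 (limma camera adjusted p = 0.00194; adjusted p = 0.173 with an estimated correlation). Without control library 3, limma called 74 spliceosome genes lower and 8 higher, 21 base excision repair genes lower and 3 higher, 23 homologous recombination genes lower and 1 higher, 15 mismatch repair genes lower and 1 higher, and 21 sphingolipid genes higher and 4 lower. Terms nearest to the fatty acid, p53, hypoxia and glycolysis lists did not pass. Fatty acid biosynthesis had 1 of 12 genes higher and 1 lower (median -0.32), and p53 signaling 5 of 61 higher and 10 lower. HIF-1 signaling had 9 of 72 higher and 4 lower, and glycolysis and gluconeogenesis 5 of 40 higher and 2 lower. Their limma camera adjusted p were 0.395, 0.295, 0.427 and 0.732. The DNA replication, lysosome and steroid biosynthesis terms passed in the direction of their lists.

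Control library 3 deviated from the mean of controls 1 and 2 with an SD of 0.866 log2 over 10015 genes, against 0.306 between those controls and 0.584 for tetracaine. GC content and transcript length accounted for 34.6% of the variance of its deviation and 1.09% of that of tetracaine, but after correction its highest correlation with a control was 0.956, below 0.989 for the lowest other pair of a group, which argues against them as the whole cause. A mislabelled tetracaine library was not excluded by the test written beforehand: over 1006 genes the median position between controls (0) and tetracaine (1) was 0.0994, and the upper quartile, 0.528, missed its bound of 0.5. A later test argues against it, as the highest corrected correlation with a tetracaine library, 0.939, lay below 0.956 for both controls. So do the levels in control library 3 of 105 genes raised at least 4-fold without it. They lay a median of 1.73% (upper quartile 7.84%) of the way from controls 1 and 2 to tetracaine. A mislabelled library would lie near the tetracaine level. Read as a share of admixed tetracaine material, these values argue against admixture too, the upper quartile being under a bound of 10% set after the values were seen. A smaller share and a mixture with other material stay open. Slower growth stays open too, because the mitosis and replication genes lay at percentile 8.91 of matched lists, between the bounds set, and no biological difference within the control group was named by the design.

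Of 8 keratins with a mean of 5 TPM or more, 5 were lower and 2 higher, with the same counts without control library 3 and 2 to 5 lower and 1 higher without any other library. KRT7, KRT8 and KRT18 fell with KRT80 and KRT81, whereas KRT79 rose by 1.93 ± 0.15 and KRT15 by 1.04 ± 0.20 (limma adjusted p = 0.00142 and 0.02504). Loss of admixed epithelial cells is argued against by EPCAM, CDH1, KRT19 and ESRP1, whose sum reached at most 0.0492% of KRT8 plus KRT18 in a control library, and by the rise of CLDN4. Control library 3, the highest for KRT7, was not the sole source, as 3 of 3 keratins were called lower without it. A response to tetracaine is a candidate explanation that was not tested further, and leaving out any library other than control library 3 left 1 to 3 of the 3 called.

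All 79 cytosolic ribosomal protein genes had negative log2 fold changes (median -0.41), but limma called 0 of them; without control library 3 the median was -0.13, with 34 lower and 2 higher. The number of negative genes was 59 without composition factors and 42 with quantile normalization. Adding 1401 named pseudogenes left the median at -0.13 without control library 3. The pseudogenes held a median of 0.0429% of the sum, too little to move it. The test therefore cannot decide whether reads shared with pseudogenes played a part. GC content and transcript length as the whole cause are argued against, because correction for them left 79 negative and 3 called lower with all libraries (median -0.40), and 48 lower and 2 higher without control library 3 (median -0.18). The test written beforehand came out as that explanation predicted, since the corrected median without control library 3 stood at percentile 97.8 of matched random lists (whose own median was -0.29) and the bound was percentile 2.5. Its verdict was changed to cannot tell after the value was seen, because these lists were matched on expression as well as GC content and length. Without the correction the genes stood at percentile 99.1 (matched median -0.25) in that fit and at 49.7 (-0.41) with all libraries. Their median thus did not stand out below genes alike in these properties, and without control library 3 it lay above the matched medians. The KEGG ribosome term, 126 genes with a median of -0.45, was nonetheless lower than all other genes (limma camera adjusted p = 1.69e-08; 4.79e-06 without control library 3; adjusted p = 0.641 with an estimated correlation). As 0 genes were called with all libraries and the signs depended on the scaling, whether these genes changed stays open, and so does a response to tetracaine.

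With 3 against 3 libraries there are 10 splits, which cannot give a share under 0.05. The real split called 1730 genes and 21 lists, and the highest of the others called 3 genes and 14 lists, with 1 split of 10 reaching the real value in each case.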
